A study of Xenopus laevis with 35 samples.

How the data were processed

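The series measured gene expression in the brain of Xenopus laevis tadpoles at Nieuwkoop and Faber (NF) stage 54, an early stage of metamorphosis. Tadpoles were kept without a chemical or exposed to MMI at 100 mg/L, PTU at 20 mg/L or PER at 4 mg/L for 24, 48 or 96 h. MMI is methimazole and PTU is propylthiouracil, both thionamide inhibitors of thyroid peroxidase, and PER is perchlorate, an inhibitor of iodide uptake by the thyroid. These names are background knowledge, since the labels give the short forms. The labels' protocols state that 10 tadpoles per treatment and time were sampled from a pair of tanks and that 3 separate pools of RNA were made. Each array therefore stands for a pool of animals, and the spread between arrays is that of pools. There were 35 arrays in 12 groups of treatment and time, with 3 arrays in each group except PER at 24 h, which had 2.

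The authors deposited 1 table of intensity values, whole numbers on a linear scale, for 898 spots. Per the labels' protocols, RNA was amplified, copied to 32P-labelled cDNA and hybridised to a 1-channel array. The scanner, the background method, any scaling between arrays and the reason for empty cells are not given in the sources used here. Between 17.3% and 44.5% of the filled cells of an array were at or below 0, so a background had been subtracted, and 677 cells were empty. The 898 spots are 2 neighbouring spots of each of 449 probes. Over probes, the rank correlation of the paired spots ranged from 0.425 to 0.754 between arrays. The probe table names a gene for 250 probes, which stand for 243 genes, and 199 probes have no gene name and are called by their ID here. For 3 genes no current symbol was found, and the array's own symbol was kept. Where several probes of a gene were measured, each was tested alone.

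The paired spots were averaged on the linear scale. The background SD of each array was taken as the root mean square of its negative probe values, and a probe was counted as above background where it exceeded 2 background SDs. Array medians over the 18 probes above background on all 35 arrays had an SD of 0.352 on the log2 scale, above the limit of 0.25 set in advance, so each array was scaled by that median. Values below 0 were then set to 0, an offset of 68.5, the 5th percentile of the positive values, was added and log2 was taken. The plan written before the data were examined gave no rule for negative values, and its rule of scaling on probes measured on all arrays was read as above background on all arrays. The other reading, a median over all probes without empty cells, was run as an alternative. Fitted changes of probes near background depend on the offset. Where all arrays of a group were below 0 they share 1 log2 value, so that group adds no spread. The p-values of such probes can then be too small. A probe above background on no array of a group has only a bound there, given as "at least N-fold" from the bright group's mean over the mean of, per array, the higher of the lowest signal above background and the probe's own, both means being taken on the log2 scale. The bright group's mean takes in its arrays below background too, so the bound is rough where few of them were above background. Such a bound is then not a strict lower limit. It also comes out larger where the arrays of the dim group are less noisy, as with PER. No fold is given where that bound is under 1 or where neither side was above background. Intensities quoted are scaled linear values.

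Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 35 arrays and 12 groups, and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. All adjusted p-values quoted are from limma. A probe needed at least 2 values in each group compared. Each compound was compared with the control of the same time and as the mean over the 3 times. Controls at 96 h were compared with controls at 24 h, MMI was compared with PTU, and the effect of each compound was tested for a difference between times. The comparisons of MMI and PTU with PER were added later. Concentrations differed between compounds and no dose series was measured.

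Genes were named by a rule fixed before the data were examined. It took up to 12 higher and 12 lower called probes per compound for the mean over times, or the 6 smallest p-values where fewer passed. It took up to 4 each way per compound and time, 2 each way in the control comparison, and all members of the thyroid hormone list. Gene lists and markers of other cell types, fixed at the same time, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, over the 341 probes with no empty cell. A gene with several probes counted in a list by its brightest probe, and lists with fewer than 3 such genes were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

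The arrays of PER 24 h replicate 1 and PER 48 h replicate 3 held nearly the same values. Their correlation over spots was 0.9999 against 0.963 for the next closest pair of arrays. After a factor of 1.045, 869 of 889 spots (97.8%) lay within 2 units, against 0.679% for that next pair, and the same 9 cells were empty. They are treated as 1 array present under 2 labels. Which label is right cannot be settled from the sources, so the fit kept both as planned. The planned comparisons and the camera tests of gene lists were run again without both. The comparisons of MMI and PTU with PER were run so only among probes above background on at least 18 arrays. Covariances of the compound effects were run again without PER 48 h replicate 3 alone, and splits of the arrays were not drawn again. PER therefore had 8 arrays of which 7 were distinct.

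The number of arrays limits the precision, and so does signal over background. Only 95 probes were above background on at least 18 arrays. Exposed arrays outnumber controls, so this choice of brighter probes favours those high with exposure. The median background SD was 1022 for control, 647 for MMI, 599 for PTU and 326 for PER arrays, in intensity units before scaling. The steps were tested on simulated data with the background noise of these arrays. Changes were planted only in probes above background on at least 18 arrays. The replicate SD was 0.367 (log2), taken from the 18 probes above background on all arrays, and noise was drawn independently for each probe. Power for dimmer probes was not tested, and real arrays may vary more than the simulated ones. For PTU averaged over times, 6, 8 and 9 of 10 probes changed 2-, 4- and 8-fold were called among 436 tested, with 1 unchanged probe called. For PTU at 96 h, 0, 5 and 6 of 10 were called among 437, with 0 unchanged. Over 50 simulated sets with no change, 0.46, 0.54 and 0.26 probes were called on average for MMI, PTU and PER averaged over times, and up to 4. The control comparison of 96 h with 24 h gave 2.98 false calls on average and up to 13, so its calls are less secure. The same holds at 24 h, where MMI and PTU gave 1.1 and 1.18 on average and up to 5 and 6. At 96 h MMI, PTU and PER gave up to 4, 3 and 3. The interaction test called 10 of 20 changed probes and 5 others among 440.

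Alternatives set in advance were the values as deposited, quantile normalization, an offset at the 20th percentile, a filter on dim probes, complete probes alone, eBayes with a trend, array weights, the replicate number as a block, the arrays of the groups compared alone, the labels' own rule of fold and replicate range, and each array left out in turn. Other alternatives were added after the data were seen: the all-probe median scaling, an offset of 1000, the 95 brighter probes alone, the shared array left out, and a mean over 24 and 48 h. Scaling matters here because it moves all probes. The median effect over all probes for PTU averaged over times was -0.18 (log2), against 0.03 after quantile normalization and 0.14 with the all-probe median. The same 3 values were -0.08, 0.03 and 0.19 for MMI and -0.16, 0.04 and 0.26 for PER. Changes are therefore relative to each scaling.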

Results

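Gene expression was measured on a small 1-channel array in the brain of Xenopus laevis tadpoles at NF stage 54. There were 9 control arrays, 9 MMI arrays, 9 PTU arrays and 8 PER arrays, with 3 per treatment and time except 2 for PER at 24 h. Each array carried 449 probes, and the number of probes above background ranged from 79 to 147 on control arrays, 86 to 241 on MMI arrays, 104 to 154 on PTU arrays and 131 to 209 on PER arrays. The background SD was highest on the control arrays, with a median of 1022 units against 647, 599 and 326 with MMI, PTU and PER. Dim probes are the most exposed to that difference. Markers of red blood cells, immune cells, muscle, and liver, pancreas and gut were represented by 1, 1, 2 and 2 genes and those of epidermis and retina by 0. None of those tested was called with any compound averaged over the 3 times, and none was above background on 18 or more arrays, so these markers could hardly show another tissue.

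**Figure D1:**
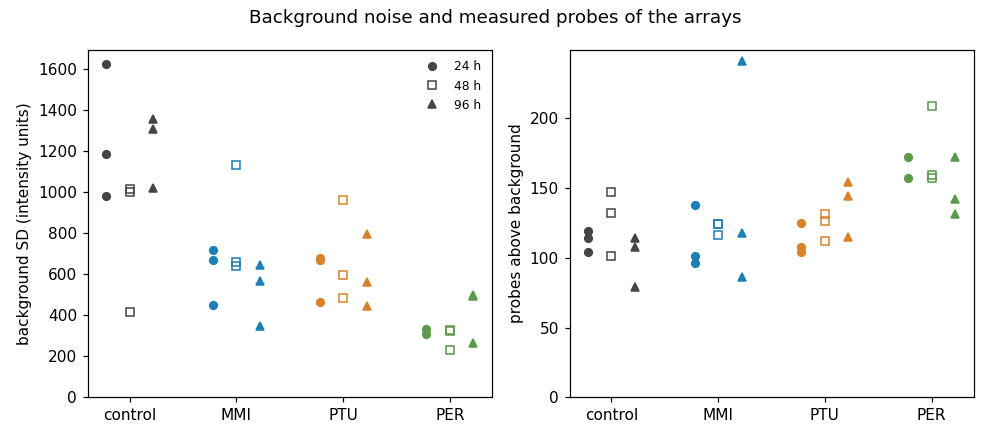
Background SD in intensity units before scaling (left panel) and number of probes above background (right panel) on each array, with control, MMI, PTU and PER arrays side by side. The median background SD was 1022 on control arrays and 326 on PER arrays.

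In the brains of MMI-exposed tadpoles, id2.L (probe 99), an inhibitor of basic helix-loop-helix transcription factors that holds back neuronal differentiation, was lower than in controls. Averaged over the 3 times its scaled intensity was 2637 ± 1651 (SD, n = 9) with MMI and 5596 ± 1459 (n = 9) in controls. The level of msi1.S (probe 337), which encodes the RNA-binding protein Musashi 1 of neural stem cells, was higher with MMI, at 3311 ± 1392 (n = 9) against 839 ± 2219 (n = 8). The level of xnf7.L (probe 827), which encodes a tripartite-motif protein that binds microtubules, was also higher, at 8133 ± 2364 against 4048 ± 3380 (n = 9 each). The comparison asks what an inhibitor of thyroid hormone synthesis does to brain transcripts, since the labels report that such exposures had enlarged the thyroid gland and delayed metamorphosis in earlier work. The change (log2) was -1.31 (SE 0.31) for id2.L, beyond the mean of the time-matched controls in that direction on 8 of 9 arrays (adjusted p = 0.0455). For id2.L the change was -2.50 at 24 h and -1.18 at 96 h, and smallest at 48 h. It was 2.61 (SE 0.62) for msi1.S on 9 of 9 arrays (adjusted p = 0.0455), a size that rests on controls of which 3 of 8 were above background. At 48 h alone the change of msi1.S was 4.67. The mean change was 2.61 for msi1.S over the 3 times. Over the 3 times the change was 1.81 (SE 0.46) for xnf7.L on 8 of 9 arrays (adjusted p = 0.0464), largely through 96 h since it was at 0.76 over 24 and 48 h alone. In all, 3 of 438 probes were higher and 2 lower, with 51 at an unadjusted p under 0.05 against 21.9 from chance. The remaining called probes have no gene name: probe 809 was higher by 1.14 (log2; adjusted p = 0.0464; 5 of 9 arrays), through 96 h since it was at -0.58 over 24 and 48 h alone, and probe 925 was lower on 9 of 9 arrays (adjusted p = 0.0455), above background on 0 MMI and 5 control arrays, with no fold given. Probe 325, the next by p, missed the threshold (adjusted p = 0.0891). The id2.L call ended after quantile normalization (-1.10, adjusted p = 0.0929) and with the all-probe median (-0.78), the xnf7.L call ended with the values as deposited (1.72, adjusted p = 0.0853), and 0 probes passed without the array shared by the PER groups or with the MMI and control arrays fitted alone. The count also fell to 0 without any 1 of 9 arrays: control 48 h replicates 1 and 3, MMI 24 h replicate 1 and all MMI arrays of 48 and 96 h. It was 1, 2 and 3 without control 24 h replicate 1, 24 h replicate 2 and 96 h replicate 1, and 8 and 9 without control 48 h replicate 2 and 96 h replicate 2.

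PTU gave more calls, led by csnk1a1.L (probe 459), which encodes casein kinase 1 alpha, a kinase of the beta-catenin destruction complex. Its scaled intensity was 4141 ± 2046 with PTU and 11906 ± 3058 in controls (SD, n = 9 each). The levels of id2.L (2028 ± 701 against 5596 ± 1459) and of dlx2.L (probe 143), a homeobox factor of forebrain interneuron development (840 ± 558 against 2325 ± 1001), were lower as well. Higher with PTU were tubb4b.L (probe 267), a beta tubulin (19938 ± 5239 against 8687 ± 1342), and msi1.S (2987 ± 1054 against 839 ± 2219). So were the glycolytic genes ldha.L (probe 763), lactate dehydrogenase A (4137 ± 1221 against 2127 ± 1346), and gapdh.S (probe 1267), glyceraldehyde 3-phosphate dehydrogenase (75409 ± 20951 against 39256 ± 7252). The change (log2) was -1.61 (SE 0.30) for csnk1a1.L (adjusted p = 0.0024; lower on 9 of 9 arrays) and -1.47 (SE 0.31) for id2.L (adjusted p = 0.00536; 9 of 9). It was 1.16 (SE 0.27) for tubb4b.L (adjusted p = 0.0122, higher on 9 of 9 arrays) and 2.55 (SE 0.62) for msi1.S (adjusted p = 0.0185, 9 of 9). The size for msi1.S rests on controls of which 3 of 8 were above background, and at 48 h alone its change was 4.06. For the glycolytic genes the change over the 3 times was 1.19 (SE 0.32) for ldha.L (adjusted p = 0.0283, 9 of 9) and 0.92 (SE 0.27) for gapdh.S (adjusted p = 0.0484, 9 of 9). Closer to background, dlx2.L was lower by a log2 change of -1.56 (SE 0.44, adjusted p = 0.0405; 8 of 9), above background on 2 PTU and 5 control arrays. The level of fmr1.L (probe 905), an RNA-binding protein of synapses, was lower by -2.88 (SE 0.64, adjusted p = 0.00973; 8 of 9), above background on 1 PTU and 3 control arrays. The transcripts ctbp2l.S (probe 93), of a transcriptional corepressor, and scnn1a.L, of an epithelial sodium channel subunit, were lower on 9 of 9 arrays each (adjusted p = 0.0024 and 0.0484) but above background on 0 PTU arrays and on 4 and 1 control arrays, so no fold is given. In total 8 of 436 probes were higher and 11 lower, with 69 at an unadjusted p under 0.05 against 21.8 from chance. Of these, 4 higher and 5 lower probes have no gene name: 637, 343, 261 and 809, and 925, 283, 745, 1135 and 1285. Probe 809 was at -0.25 over 24 and 48 h alone. After quantile normalization the split was 9 higher and 3 lower, and with the all-probe median 11 and 3. Under quantile normalization gapdh.S changed by 0.20 (adjusted p = 0.770), id2.L by -0.97 (adjusted p = 0.104), and the calls of fmr1.L (-2.34, adjusted p = 0.0694) and dlx2.L were lost. With the all-probe median those of csnk1a1.L (-1.01, adjusted p = 0.135), id2.L (-0.87) and dlx2.L were lost. The ldha.L call was lost without control 24 h replicate 3, PTU 48 h replicate 2 or PTU 96 h replicate 1 (adjusted p = 0.0593, 0.0524 and 0.0575), and those of gapdh.S, dlx2.L and scnn1a.L were kept in 10, 13 and 11 of 31 alternatives each. Over 24 and 48 h alone 0 probes were higher and 8 lower, tubb4b.L being at 1.04 (adjusted p = 0.0885), msi1.S at 2.54 (adjusted p = 0.0545) and ldha.L at 0.44 (adjusted p = 0.676). The number of calls was 7 with the PTU and control arrays fitted alone, 30 without control 96 h replicate 3 and 12 without PTU 96 h replicate 1.

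Perchlorate, which acts on iodide uptake and not on thyroid peroxidase, gave calls in id2.L, dlx2.L and msi1.S. The level of id2.L was 2294 ± 1226 with PER (SD, n = 8) against 5596 ± 1459 in controls (n = 9), and that of dlx2.L was 629 ± 432 against 2325 ± 1001. The level of msi1.S was higher, at 3468 ± 646 (n = 8) against 839 ± 2219 (n = 8). Of the 8 PER arrays 7 were distinct. The change (log2) was -1.48 (SE 0.32, adjusted p = 0.0134) for id2.L, -1.95 (SE 0.46, adjusted p = 0.0148) for dlx2.L and 2.82 (SE 0.65, adjusted p = 0.0134) for msi1.S, each in that direction on 8 of 8 arrays. The size for msi1.S rests on controls of which 3 of 8 were above background, and at 48 h alone its change was 4.42. The level of ctbp2l.S was called lower (adjusted p = 0.0134, 8 of 8 arrays), above background on 0 PER and 4 control arrays. Its bound of 1.42-fold is rough, since most controls were below background and PER arrays were the least noisy. Among probes with no gene name, 357 was higher by 1.47 (log2; SE 0.33; adjusted p = 0.0134; 8 of 8 arrays), at 42598 ± 17032 against 15807 ± 5789. Probe 809 was higher by 1.65 (adjusted p = 0.00378, 4 of 8), through 96 h since it was at -0.42 over 24 and 48 h alone. Probe 325 was called lower (adjusted p = 0.0134, 7 of 7 arrays with a value), with a rough bound of 1.78-fold. It was above background on 0 PER and 4 control arrays. In total 3 of 439 probes were higher and 4 lower, with 56 at an unadjusted p under 0.05, and after quantile normalization 17 were higher and 4 lower. Without both copies of the shared array 0 probes passed, id2.L being at -1.42 (adjusted p = 0.0824) and msi1.S at 2.82 (adjusted p = 0.0824). The count was also 0 without PER 24 h replicate 1, was 2 with the PER and control arrays fitted alone or over 24 and 48 h alone, and was 13 without control 96 h replicate 3. The call of id2.L also ended after quantile normalization (-0.92, adjusted p = 0.113) and with the all-probe median (-0.90), as did that of dlx2.L, which was also lost without PER 24 h replicate 2.

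**Figure D2:**
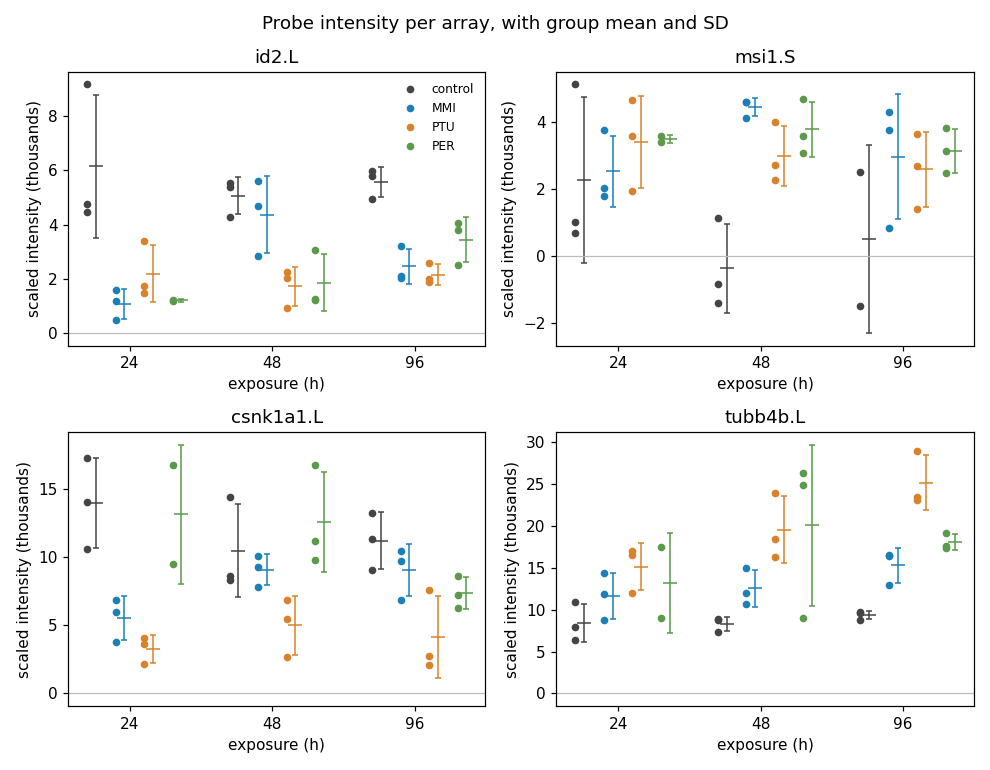
Scaled intensity divided by 1000 of id2.L, msi1.S, csnk1a1.L and tubb4b.L by treatment and time; points are arrays, and the dash and bar are the mean and SD of a group. Over the 3 times id2.L averaged 5596 in controls and 2028 with PTU, and csnk1a1.L averaged 11906 and 4141; the id2.L calls ended under quantile normalization and with the all-probe median, and that of csnk1a1.L with the all-probe median.

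At 24 h, id2.L was already lower with MMI, at 1081 ± 561 against 6144 ± 2627 in controls (SD, n = 3 each), and so was rpl35a.S, a protein of the large ribosomal subunit, at 353 ± 1348 against 4476 ± 1273. With PTU, xpa.L, a DNA damage recognition factor, was at least 2.82-fold lower and dcc.L, the netrin receptor of axon guidance, at least 1.97-fold lower (adjusted p = 0.0412 for both; 3 of 3 arrays). Both were above background on 0 PTU arrays, and on 3 and 1 of 3 control arrays, so the bound for dcc.L is rough. Across the brighter probes the control arrays of 24 h had mean correlations of 0.583 to 0.606 with the others of their group, against 0.756 to 0.802 with MMI and 0.804 to 0.842 with PTU, and background SDs of 981 to 1627. The changes with MMI (log2) were -2.50 (SE 0.54, adjusted p = 0.0137) for id2.L and -4.40 (SE 0.96, adjusted p = 0.0137) for rpl35a.S, lower on 3 of 3 arrays, of which 1 was above background for each gene. The adipogenic nuclear receptor gene pparg.L was called lower with both thionamides without being above background on any array compared. Its fitted change was identical with both, since values below 0 were set to 0, so the exposed arrays added no spread. The other PTU calls were probe 623, at least 1.94-fold lower (adjusted p = 0.0412), and, chosen after their values were seen, csnk1a1.L (-2.10), fmr1.L and probe 283. In limma, 0 probes were higher and 3 lower with MMI (53 of 440 at an unadjusted p under 0.05), 0 and 7 with PTU (64 of 439) and 0 and 0 with PER (37 of 439). Sets simulated with no change gave up to 5 calls with MMI and up to 6 with PTU at 24 h. At 48 h limma called 0 probes with each compound, with 22, 32 and 26 at an unadjusted p under 0.05 for MMI, PTU and PER. The 24 h calls of MMI and PTU all ended after quantile normalization, with id2.L at -1.49 and rpl35a.S at -3.44 with MMI and csnk1a1.L at -1.69 with PTU (adjusted p = 0.484, 0.28 and 0.179), and with the all-probe median (-1.33, -3.47 and -1.20). They also fell to 0 without control 24 h replicate 1 (MMI), control 24 h replicate 3 (both), MMI 24 h replicate 3, and PTU 24 h replicates 1 or 3, and to 1 without MMI 24 h replicate 2. At 48 h 1 probe was called with each compound without control 48 h replicate 2, and with PER also without PER 48 h replicate 3.

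At 96 h the calls were mostly of higher levels in exposed brains, and xnf7.L and btg1.S, an antiproliferative gene, were called with all 3 compounds. The level of xnf7.L was 6528 ± 157 with MMI, 5063 ± 1470 with PTU and 5322 ± 147 with PER against 1127 ± 2154 in controls (SD, n = 3 each), of which 1 was above background. The gene of the appetite peptide neuropeptide Y, npy.S, was at least 1.55-fold higher with MMI (3616 ± 1206 against -227 ± 1929; adjusted p = 0.0067) and at least 1.34-fold higher with PER (3075 ± 771; adjusted p = 0.0191). The level of ldha.L was at least 2.35-fold higher with PTU (5457 ± 1374 against 963 ± 783; adjusted p = 0.00856). The prolactin receptor gene prlr.L was called lower with PER (adjusted p = 0.0191) and with MMI with no fold given (adjusted p = 0.0188). Its bound with PER, 1.94-fold, is rough, since 2 control arrays had a value and 1 was above background. All these directions held on 3 of 3 exposed arrays. The 3 control arrays of 96 h, on which all these calls rest, stood apart from each other: across the brighter probes their mean correlation with the others of their group was 0.373, 0.511 and 0.417, against 0.753 to 0.935 for the exposed arrays of 96 h. The change (log2) of xnf7.L was 3.92, 3.52 and 3.63 with MMI, PTU and PER (adjusted p = 0.00574, 0.0164 and 0.0153), and that of btg1.S has no fold, since 0 control arrays were above background (adjusted p = 0.0067, 0.0159 and 0.033). With MMI, map2k3, a kinase upstream of p38, was at least 1.60-fold higher and probe 633 at least 1.39-fold higher (adjusted p = 0.0067 each). Lower with MMI were pkmyt1.S, an inhibitory kinase of CDK1 (adjusted p = 0.0441), and probe 355, with no fold given, and probe 589. The bound of 1.16-fold for probe 589 is rough, since 1 of 3 control arrays was above background. Probe 809 was higher with all 3 compounds, by at least 1.26-fold with PTU and 1.65-fold with PER, with no fold for MMI. Chosen after their values were seen, cct3.S, a chaperonin subunit, was higher by 1.62 with MMI (8130 ± 356 against 2658 ± 707; adjusted p = 0.0441) and 2.06 with PTU (adjusted p = 0.017), lmo3.S by 3.14 and casp1.L by 2.98 with MMI, and ldha.L was higher with PER with no size given (5073 ± 1146; adjusted p = 0.0137). In limma, 17 of 438 probes were higher and 4 lower with MMI (61 at an unadjusted p under 0.05), 5 of 437 and 0 with PTU (49) and 5 of 440 and 1 with PER (48). Over the brighter probes the median change was 0.92, 0.33 and 0.58 (log2) with MMI, PTU and PER, and 0.26, 0.31 and 0.63 with the values as deposited. With those values MMI gave 6 and 2, and with only the arrays compared in the fit the calls were 0 with MMI, 0 with PTU and 1 with PER (probe 809). For PTU another split of the 6 arrays gave 10 calls. The MMI count was 9, 13 and 13 without MMI 96 h replicates 3, 1 and 2 and 11 without control 96 h replicate 1. The PTU count was 2 without PTU 96 h replicates 2 or 3 and 17 without control 96 h replicate 3. The PER count was 2, 3 and 1 without PER 96 h replicates 1, 2 and 3 and 13 without control 96 h replicate 3.

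**Figure D3:**
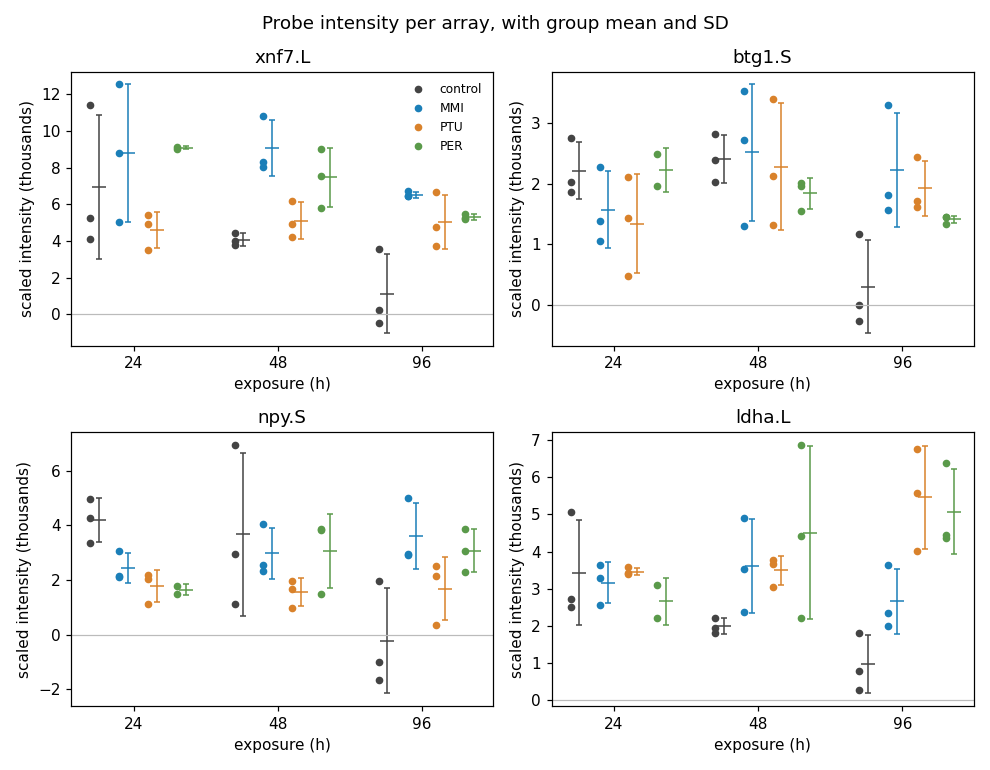
Scaled intensity divided by 1000 of xnf7.L, btg1.S, npy.S and ldha.L by treatment and time; points are arrays, and the dash and bar are the mean and SD of a group. At 96 h xnf7.L averaged 1127 in controls and 6528 with MMI.

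In untreated brains, more probes were called lower than higher at 96 h against 24 h. The DNA repair gene xpa.L was at least 1.86-fold lower (adjusted p = 0.00594; 3 of 3 arrays) and frat1.S, an activator of Wnt signalling, at least 1.44-fold lower (adjusted p = 0.0148; 3 of 3). Probe 187, with no gene name, was at least 1.61-fold higher (4891 ± 2517, SD, n = 3; adjusted p = 0.00425; 3 of 3), and prlr.L was called higher with no fold given (adjusted p = 0.00873; 2 of 2 arrays with a value). Named after their values were seen, xnf7.L and cct3.S had lower levels at 96 h, by a log2 change of -3.87 and -1.86, and ldha.L, npy.S and btg1.S, above background on 0 control arrays at 96 h, were lower too. In limma 3 of 440 probes were higher and 21 lower, with 80 at an unadjusted p under 0.05 against 22 from chance. Of the 18 probes higher at 96 h with at least 1 compound, 12 were also among those lower in controls, but both comparisons use the same 3 control arrays of 96 h, whose noise enters both. The split was 3 and 10 after quantile normalization and 2 and 5 with the all-probe median, and 0 probes were called with only these arrays in the fit.

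The compounds were set against each other at doses that differed (100, 20 and 4 mg/L). For id2.L the difference MMI minus PTU (log2) was 0.16 (95% interval -0.48 to 0.80), MMI minus PER 0.17 (-0.50 to 0.83) and PTU minus PER 0.01 (-0.66 to 0.67). For msi1.S these differences were 0.06 (-1.17 to 1.29), -0.21 (-1.49 to 1.07) and -0.28 (-1.56 to 1.00). The kinase gene csnk1a1.L was lower with PTU than with PER by a log2 difference of -1.47 (-2.12 to -0.82; adjusted p = 0.0117). Between the thionamides its difference, MMI minus PTU, was 1.01 (0.38 to 1.63) and missed the threshold (adjusted p = 0.222). In limma 0 of 434 probes differed between MMI and PTU (48 at an unadjusted p under 0.05) and 0 of 437 between MMI and PER (33). Between PTU and PER 2 of 436 were higher and 2 lower (35 at an unadjusted p under 0.05). Both higher probes were of rpl8.S, a ribosomal protein gene, at 1.30 and 1.31 (adjusted p = 0.0105 each), and the lower ones were csnk1a1.L and probe 745 (-1.40, adjusted p = 0.0243). The other 3 probes of rpl8.S were at 1.00, 0.68 and 0.66 and were not called. All 4 calls ended after quantile normalization, where the rpl8.S probes were at 0.75 and 0.58 (adjusted p = 0.235 and 0.417) and csnk1a1.L and probe 745 at -1.27 and -1.30 (adjusted p = 0.086 each). They also ended with the all-probe median, at 1.32, 1.33, -1.45 and -1.38 (adjusted p = 0.258 each). PER held the shared array under 2 labels, and over all probes its comparisons with MMI and PTU were not run without that array.

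Of the 6 genes of the thyroid hormone list on the array (nfib.L, rxrb.L, thdl17.L, thdl18.S, thibz.L and klf9.L), 0 were called over all probes with any compound averaged over times. Only nfib.L was above background on 18 or more arrays. The level of klf9.L, a Kruppel-like factor gene induced by thyroid hormone, was above background on 3 of 9 control arrays and on 0 exposed arrays, below the control mean on all 9, 9 and 8 arrays with MMI, PTU and PER (adjusted p = 0.0891, 0.268 and 0.0667). Adjusted over the list alone, 1 gene was called with MMI (klf9.L), 0 with PTU and 2 with PER (klf9.L and thdl18.S), all lower. The values of thibz.L, a leucine zipper gene induced by thyroid hormone, were 0.21, -0.21 and -0.85 (log2, not called), with 0 or 1 array above background in each treatment. The camera test gave adjusted p = 0.348, 0.368 and 0.109 for the list with MMI, PTU and PER, and 0.412, 0.523 and 0.27 with an estimated correlation. With fry, which asks whether the genes moved on balance one way, the list was lower with PTU (adjusted p = 0.0423) and PER (adjusted p = 0.0165) and not called with MMI (adjusted p = 0.113), though it was lower with MMI at 24 h (adjusted p = 0.0131). There camera gave adjusted p = 0.165, and 0.303 with an estimated correlation. Since control arrays had the higher background SD, levels of such dim genes carry that difference too. The list does not separate genes that thyroid hormone raises from genes that it lowers. A shared direction over it is therefore not read as a response to less hormone.

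Among the other gene lists, with each compound averaged over times unless a time is named, neural development transcription factors had 16 genes tested, of which id2.L was lower with MMI and id2.L and dlx2.L with PTU and PER, with 0 higher. The energy metabolism list had 9 genes tested with PTU, of which ldha.L and gapdh.S were higher and 0 lower (2 when adjusted over the list alone; camera adjusted p = 0.432). The kinase signalling list had 32 tested, with csnk1a1.L lower with PTU, the cytoskeleton list had 4, with tubb4b.L higher with PTU, and the neuronal list had 10, with 1 lower with PTU, scnn1a.L, an epithelial sodium channel gene. The cell cycle list had 19 tested and 0 called with each compound averaged over times, 3, 1 and 0 adjusted over the list alone, and 1 lower with MMI at 96 h (pkmyt1.S). By their symbols some lists took in genes of other functions: pkmyt1.S in the neural and energy lists, the kinase gene rps6ka3.L in the ribosome list, smad2.L of growth factor signalling in the cell cycle list and katna1.S of microtubule severing in the chromatin list. The hormone list had 8 genes, of which npy.S and crhbp.S, a binding protein of corticotropin-releasing hormone above background on 1 array of 35, were higher and prlr.L lower with MMI at 96 h. In the other lists, of nuclear receptors, apoptosis, myelin and glia, extracellular matrix, stress, ribosome, and chromatin, 0 genes were called with any compound averaged over times. Over 144 tests of a list in a comparison, camera called 0, 0 with an estimated correlation, while fry called 10 for 1 direction and 3 for a change in either direction. The myelin gene mbp.S was at 0.79, 0.75 and 0.76 (log2) with MMI, PTU and PER and was not called (adjusted p = 0.570, 0.500 and 0.554).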

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

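The tests of single control arrays, of the brightness of the control arrays, of the change with time in untreated tadpoles and of the noise of the control arrays were chosen after the results were seen.

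The effect of exposure differed between times for 7 combinations of a probe and a compound, by limma's test of the difference itself. Probe 809, which has no gene name, differed with MMI (adjusted p = 8.50e-06), PTU (adjusted p = 2.02e-06) and PER (adjusted p = 4.77e-07), its effect being higher at 96 h than at 24 h with each. With MMI the effect was also higher at 96 h than at 24 h for map2k3, a kinase upstream of p38 (adjusted p = 0.0139), and for probes 1173 (adjusted p = 0.0191) and 909 (adjusted p = 0.0211), by 3.69 and 3.66 (log2) for the latter pair. With PTU the effect on fzd2.S, a Wnt receptor gene, was lower at 48 h than at 24 h (adjusted p = 0.0161). No size is given for map2k3 and fzd2.S, above background on 4 and 5 arrays of 35, and for probe 809, above background on 0 control arrays at 24 and at 96 h. The 96 h controls of probe 809 were below 0 (-742 ± 208, SD, n = 3), so they share 1 log2 value and add no spread. Its SE with MMI at 96 h was 0.50, against a median of 1.33 over all probes, so its p-values can be too small. Probes 1173 and 909 were above background on 33 arrays each. Chance cannot be excluded for the MMI and PTU counts: 8 of 100 splits within times gave as many as the 4 calls of MMI (highest other 10), and 29 of 100 as many as the 2 of PTU (highest other 5). The MMI count was 1 without MMI 96 h replicate 1, 7 without control 48 h replicate 1 and 8, 10 and 13 without control 96 h replicates 1, 2 and 3.

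At 96 h, 18 probes were higher than in controls with at least 1 compound, in 27 calls, 3 of them (xnf7.L, btg1.S and probe 809) with all 3 compounds. A single control array is argued against as the whole source: without control 96 h replicate 1, 2 or 3 the median log2 change was 86.3%, 88.6% or 96.9% of its value, though 14, 19 and 25 of 27 calls were still made with fewer arrays. A uniformly lower brightness of the control arrays over all probes is argued against as well, since after quantile normalization the median was 102% of its value and 24 calls were still made. With the values as deposited 14 were made (89.7%) and 19 with the all-probe median (97.0%). A dimming of the brighter probes alone in these controls cannot be excluded this way. After quantile normalization the median change of all brighter probes at 96 h was still 0.78, 0.50 and 1.03 (log2) with MMI, PTU and PER. A rise over these probes is partly built in, since their choice favours probes high on the more numerous exposed arrays. In controls the median fitted change of these probes from 24 to 96 h, which depends on the offset, was -2.78, against 1.07, -1.37 and -0.04 with MMI, PTU and PER, so the largest fall in an exposed group was 49.5% of that in controls. A fall in the controls is partly built in, since the probes were chosen for low levels in the same 3 control arrays at 96 h, so a change with time in untreated tadpoles cannot be told apart from something particular to those arrays, which also correlated poorly with each other (0.373 to 0.511).

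Effects shared by the compounds were the next pattern: of the probes called in the mean over times, 2 were higher with both MMI and PTU, 2 with MMI and PER and 2 with PTU and PER, and 2, 1 and 3 were lower, id2.L in each pair. Independent lists would give 0.0484, 0.0206 and 0.055 higher and 0.0507, 0.0183 and 0.101 lower, but with shared controls the lists are not independent. The covariance of the effects over 341 probes was 0.561, 0.584 and 0.606, and 0 of 3 pairs lay above the central 95% of sets simulated without any effect (upper bounds 1.05, 1.07 and 1.07), so the shared control arrays alone could give a covariance of that size. Over the brighter probes 0 of 3 pairs did so too, which leaves a higher background of the control arrays open. With the controls split between the compounds the covariance had medians of 0.0997, 0.141 and 0.154, above 0 as an action common to the 3 exposures would give, yet a difference between all control arrays and all others would give the same. Single splits ranged from -0.03 to 0.27 for MMI and PTU, 0.03 to 0.30 for MMI and PER and 0.03 to 0.29 for PTU and PER. Over the brighter probes the lowest values were -0.07, -0.06 and 0.05.

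Probes near background were lower with exposure in the scaling used: over 347, 344 and 346 probes above background on fewer than 18 arrays, the median change was -0.31, -0.32 and -0.26 (log2) with MMI, PTU and PER. They were smaller after quantile normalization, at -0.13, -0.08 and -0.13, and with the all-probe median, at -0.08, -0.02 and 0.05, where the direction turned for PER. Sets simulated with the noise of each array and no change gave -0.07, -0.09 and -0.11. The higher background noise of the control arrays could thus account for part of it, in the observed direction (highest of the 3 medians -0.26), while the simulated sizes were smaller than the observed ones and no biological explanation was tested. The choice of these probes leans the same way. A probe high on only the 9 control arrays always falls among them, while a probe high on only the exposed arrays can pass 18 arrays. The simulated sets kept the choice made on the real values, so they cannot show how much this adds. Of the calls of lower levels over times it concerns 1 with MMI (probe 925), 6 with PTU (probes 925 and 1135, ctbp2l.S, fmr1.L, scnn1a.L and dlx2.L) and 3 with PER (probe 325, ctbp2l.S and dlx2.L).

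Splits of the same arrays into other groups were counted for each comparison. For the mean over times a random split of the arrays is argued against for PTU, with 19 calls against at most 7 in the others of 100 splits. The splits cannot exclude differences between tanks or arrays that went with the treatment. With the PTU and control arrays fitted alone the count was 7, and the splits were not drawn again in that fit. For PER the real count was 7 against 3, but both labels of the shared array entered, and the count was 0 without both copies, 0 without PER 24 h replicate 1 and 10 without PER 48 h replicate 3. The splits were not drawn again without that array, so chance is left open for PER. For MMI 2 of 100 splits, the real one included, gave as many as its 5 calls (highest other 5), a share of under 5%. For MMI against PTU, with 0 calls in limma and 48 probes at an unadjusted p under 0.05, all 100 splits gave as many (highest other 1). For a single time the 6 arrays make only 10 splits, too few for a share under 5%. There the real and highest other counts were 3 and 3 for MMI at 24 h (2 splits as large), 21 and 3 for MMI at 96 h (1), 7 and 3 for PTU at 24 h (1), 5 and 10 for PTU at 96 h (2), 6 and 0 for PER at 96 h (1), and 24 and 15 for controls over time (1). At 48 h the counts were 0 and 0 for MMI, PTU and PER (10 splits each), with 22, 32 and 26 probes at an unadjusted p under 0.05 in limma.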

How the results depend on the processing

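The all-probe median scaling, the offset of 1000, the 95 brighter probes alone, the shared array left out and the mean over 24 and 48 h were alternatives chosen after the data were seen.

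Under the alternatives planned, named probes kept their side of the threshold in 533 settings, lost a call in 139, gained one in 4 and reversed a called direction in 0. Named probes without a call in the main fit, such as those of the thyroid hormone list, count as kept while uncalled, even where their direction turned. The share of calls lost is therefore higher than these numbers give. With 1 array left out the numbers were 804, 224, 7 and 0. Under the added alternatives they were 242, 70, 4 and 3, the 3 reversals being of probe 809 over 24 and 48 h alone (-0.58 with MMI, -0.25 with PTU and -0.42 with PER), whose calls rest on 96 h. With PTU, csnk1a1.L kept its call in 31 of 32 alternatives, tubb4b.L in 30 of 32 and id2.L in 30 of 32, while with MMI id2.L kept its call in 12 of 32. With PTU ctbp2l.S kept its call in 31 of 31, but it was above background on 0 PTU and 4 control arrays. It is not among the 95 brighter probes, so that alternative left it out. The call of klf9.L with PER, missed over all probes, was gained in 8 of 29. Among the planned comparisons, counts of called probes that moved by over 1.5 times are given by alternative. The cause was not tested, except that the labels' rule has no test and that fewer probes or arrays enter where so named. Few probes exceeded background on most arrays, and whether that moved the counts was not tested. With the values as deposited the counts were 1 (MMI 48 h), 8 (MMI 96 h), 2 (PTU 24 h), 3 (MMI mean over times) and 2 (MMI difference between times). After quantile normalization they were 0 (MMI 24 h), 0 (PTU 24 h), 1 (PER 24 h), 12 (PTU mean), 21 (PER mean) and 13 (controls over time). With the offset at the 20th percentile (275) they were 1 (MMI 48 h), 12 (PTU 24 h), 1 (PTU 48 h), 2 (PER 24 h), 15 (PER mean) and 10 (MMI between times). Without the dimmest probes, those under the 25th percentile, they were 1 (MMI 48 h), 1 (PER 24 h), 15 (PER mean) and 10 (MMI between times). With complete probes alone the count was 2 (MMI between times). With an eBayes trend they were 1 (MMI 48 h), 12 (PTU 24 h), 1 (PTU 48 h), 12 (PTU 96 h), 2 (PER 24 h), 2 (PER 48 h) and 11 (PER 96 h). For the rest they were 3 (MMI mean), 18 (PER mean), 6 (MMI against PTU), 14 (MMI between times) and 5 (PTU between times). With array weights they were 0 (MMI 24 h), 9 (MMI 96 h), 0 (PTU 24 h), 3 (PTU 96 h). Over times they were 1 (MMI mean), 10 (PTU mean), 5 (controls), 4 (MMI against PTU) and 1 (MMI between times). With the replicate number as a block the MMI mean gave 0; arrays of 1 number did not pair, with a mean r of 0.0128 against -0.00916 for other pairs. With only the arrays compared, and so fewer arrays for the spread, they were 1 (MMI 24 h), 0 (MMI 96 h), 2 (PTU 24 h), 0 (PTU 96 h), 1 (PER 96 h). Over times they were 0 (MMI mean), 7 (PTU mean), 2 (PER mean), 0 (controls), 1 (MMI against PTU) and 1, 1 and 2 (MMI, PTU and PER between times). The labels' rule of fold and range gave 29, 12 and 1 for MMI (24 h, 48 h, mean), 18, 28, 15 and 6 for PTU (24 h, 48 h, 96 h, mean). It gave 36, 23, 16 and 4 for PER, 15 for controls and 2 for MMI against PTU. With the all-probe median they were 0 (MMI 24 h), 0 (PTU 24 h), 2 (PTU 96 h), 3 (MMI mean), 7 (controls), 2 (MMI between times) and 1 (PTU between times). With the offset of 1000 they were 12, 1 and 9 for MMI (24 h, 48 h, mean), 26, 2 and 11 for PTU (24 h, 48 h, 96 h). They were 7, 4, 13 and 22 for PER (24 h, 48 h, 96 h, mean), 45 for controls, 4 for MMI against PTU and 19 and 4 for MMI and PTU between times. With the 95 brighter probes alone, and so fewer tests and a spread estimated from brighter probes, they were 7, 1 and 10 for MMI (24 h, 48 h, mean), 5 and 14 for PTU (48 h, 96 h). They were 3, 3, 17 and 21 for PER (24 h, 48 h, 96 h, mean), 15 for MMI against PTU and 24, 5 and 4 for MMI, PTU and PER between times. Without both copies of the shared array, so with fewer arrays, they were 1 (PER 48 h), 0 (MMI mean), 0 (PER mean), 2 (PER between times) and 2 gene lists, both lost with an estimated correlation (adjusted p = 0.149). Over 24 and 48 h alone they were 0 (MMI), 8 (PTU) and 2 (PER). For the gene lists, where camera called 0, fry called 10 by direction and 3 in either direction. With the controls split the covariances of the 3 compound pairs were 0.0997, 0.141 and 0.154.

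With 1 array left out at a time, calls ranged from 0 to 3, 0 to 1, 9 to 31 and 0 to 9 for MMI (24 h, 48 h, 96 h, mean), from 0 to 7, 0 to 1, 2 to 17 and 12 to 30 for PTU, and from 0 to 0, 0 to 1, 1 to 13 and 0 to 13 for PER. They ranged from 18 to 33 for controls over time, 0 to 0 for MMI against PTU, 1 to 13, 1 to 5 and 1 to 4 for MMI, PTU and PER between times, and 0 to 2 for gene lists. Where PER 24 h was left with 1 array, it was assumed to vary like the other groups. Without MMI 24 h replicate 3, MMI 96 h replicate 3, PTU 24 h replicate 1 and PER 24 h replicate 1 camera called 2, 1, 1 and 2 lists, all lost with an estimated correlation (adjusted p = 0.127, 0.135, 0.0875 and 0.123). The PTU count between times was 1 without control 48 h replicate 1 or PTU 48 h replicates 1 or 3, 4 without control 96 h replicates 1 or 2 and 5 without control 96 h replicate 3. That of PER was 3, 4 and 2 without control 96 h replicates 1, 2 and 3 and 2 without PER 48 h replicate 3.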

Other observations

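The test on the 95 brighter probes alone was chosen after the data were seen, and the genes in this part were named after their values were seen.

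Among the 95 probes above background on at least 18 arrays, the adjustment runs over fewer probes, the moderated spread is smaller and more probes pass with MMI and PER, while PTU has 19 calls either way. For gapdh.S with PTU, for example, the SE was 0.170 against 0.266 over all probes. With MMI averaged over times, ldha.L (0.80, log2) and tubb4b.L (0.58) were then called higher beside msi1.S and xnf7.L, as was coro1c.L (1.04), an actin-binding coronin (adjusted p = 0.044, 0.0443 and 0.0283). With PER, ldha.L (1.11), tubb4b.L (0.89) and pabpc1.S (1.03), the poly(A)-binding protein, were called higher (adjusted p = 0.00358, 0.0017 and 0.0017). At 96 h gap43.S, a protein of axonal growth cones, was called higher with each compound, by 1.74, 2.09 and 2.06 (adjusted p = 0.0157, 0.00729 and 0.0077), though not with MMI after quantile normalization (adjusted p = 0.0707). With the values as deposited gap43.S at 96 h and coro1c.L, ldha.L and tubb4b.L over times were not called with MMI (adjusted p = 0.242, 0.0576, 0.103 and 0.194). These genes have adjusted p-values above 0.05 over all probes in the same comparisons, from 0.0719 for pabpc1.S and for ldha.L with PER to 0.388 for tubb4b.L with MMI. The 7 named probes called lower over times with PER were of ldhb.S (-0.89), rpl35a.S (-2.09), nme2.L (-0.59), id2.L and rpl8.S. With PTU ldhb.S was called lower too (-0.63, adjusted p = 0.0358). After quantile normalization ldhb.S was at -0.06 with PTU and -0.37 with PER and was not called. The counts for the mean over times were 8 higher and 2 lower with MMI, 11 and 8 with PTU and 12 and 9 with PER. The lean to higher is partly built in, since the choice of probes favours those high on the more numerous exposed arrays. After quantile normalization they were 21 and 2, 16 and 3, and 27 and 6, and without the shared array PER gave 8 and 4. Between MMI and PTU 9 were higher and 6 lower, but 0 and 0 after quantile normalization, where limma was used as before. Between MMI and PER 8 were higher and 4 lower, with 4 and 6 after quantile normalization and 1 and 2 without the shared array. Between PTU and PER 6 were higher and 6 lower, with 3 and 6 after quantile normalization and 3 and 3 without the shared array.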
